A study of Mus musculus with 24 samples.

How the data were processed

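RNA was measured in 24 samples of mouse bone marrow-derived macrophages, 8 in the antagonist and 16 in the memory experiment, in 12 groups of 2. Per the labels' protocols, marrow cells of C57BL/6 mice aged 3 months were differentiated for 6 days with M-CSF. For the antagonist experiment they received a DMSO and ethanol vehicle, IL-4, GW9662 or both for 24 h, and the labels give no dose of GW9662. For the memory experiment, wild-type and knockout-labelled cells had IL-4 for 24 h or none, were washed and kept for 24 h in differentiation medium, and then had IL-4 for 3 h or none. The labels give the IL-4 dose as 20 ng per µl, which is printed here as labelled. Per the labels' protocols, RNA was taken with Trizol and made into poly-A libraries that were sequenced on an Illumina HiSeq. Per the submitters' processing notes, TopHat2 2.0.7, Cufflinks 2.0.2 and the mm10 genome were used, and the notes do not say what each of them did to the tables.

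The deposited tables, 1 per experiment, hold 23420 genes and 1 column per group. Their unit is signal as recorded here, since the authors deposited means of both samples of a group, as reads scaled to library size (CPM), with no spread. The columns add up to 951943 to 1054527 in the antagonist and 957489 to 1022961 in the memory table. No column holds the value of a single sample.

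Before the data were examined, the comparisons, the gene lists, the rule for named genes and most alternatives were fixed. For averaged columns that plan took log2 of the ratio of means with 1 CPM added to each, genes with a mean of at least 1 CPM in either group, and counts beyond 2-fold each way, with no test. The same plan foresaw limma if values of single libraries could be had. Of the 20 comparisons, 15 set a pair of groups side by side and 5 set responses against each other. The groups of the same table were compared, and the tables were never joined.

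Once the values had been seen, each averaged column was found to be built from whole read counts of 2 libraries, each with its own step. The step of each library was estimated from the low values, and each value was then separated into a pair of whole counts. Of 171808 values above 0, 169591 (98.7%) had 1 solution, 944 were settled as the plausible choice among a few, and 1273 stayed unresolved. On simulated tables, 163472 of 163472 values with 1 solution and 2755 of 2755 plausible ones were right. In 4 groups, 81 plausible separations were set back to unresolved. A plausible choice assumes 2 like libraries, and these groups mix the counting kinds described below. The simulated libraries had no counting kinds, so they do not check plausible choices in such groups. The libraries of a group are called deeper and shallower, and their replicate numbers are not known. One read equals a different CPM in each library, and 3 reads correspond to 0.105 to 0.181 CPM in the antagonist and 0.183 to 0.526 CPM in the memory libraries. Reads in genes came to 15766734 to 27973240 and 5444284 to 16476513 per library.

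The test that decides "rose" and "fell" was added after the data were seen. It is limma-trend 3.58.1 (R 4.3.3) on log2 of CPM plus 1 of the separated libraries, with 1 coefficient per group, all libraries of the table, 1 weight per group and a BH adjusted p under 0.05. An unresolved value entered as 1 observation of weight 2, but was left out of the fit with counting kind (described below) as a term. A first version had no group weights. It was replaced after simulation, in which it placed 24.4% of its calls on unchanged genes for IL-4 against vehicle, and the weighted version 12.5%. For the first wild-type exposure the shares were 0.0% and 4.9%. Beyond counting noise, the simulation gave all genes of a group the same spread, which is the form that group weights assume. It held no counting kinds and no trend with transcript length. Simulated counts of calls on unchanged genes, here and below, therefore do not measure how often real calls are false. The weights were 0.21 for the IL-4 group, 0.08 for the restimulated wild-type group and 0.84 to 2.66 for the others. In simulated tables the weighted test found 16.4%, 59.7% and 92.4% of genes changed by 1.5, 2 and 4-fold for IL-4 against vehicle. For the first wild-type exposure it found 71.2%, 94.0% and 98.5%. Those tables held 200 changed genes each, in the IL-4 group or in first-exposed wild-type cells. Comparisons without these groups held no change. The planned count test on recovered reads was run as limma-voom. In it unresolved values entered as their most plausible pair of counts, which are not recovered reads. Tests within a list were also adjusted over the list alone. The planned limma camera test of lists was not run, and list medians carry the percentile among 10000 random lists matched in 20 bins of expression as a description only.

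Libraries fell into 2 counting kinds. They were told apart by 185 genes that share at least 50% of their sampled 50-base words with transcripts of other genes. Summed over these genes, 14 libraries gave 8226 to 9408 CPM and 10 gave 12608 to 17340 CPM, named low and high kind. Genes at least 1.5-fold higher in the high-kind library in every mixed group where they were separated, and in at least 2 such groups, were set aside as sensitive to counting. They number 473 (340 at 2-fold), 58 of them ribosomal protein genes, with a median of 29.5% shared sequence against 0.49% in other genes. Of the table's names, 23283 were found in the reference tables (GENCODE release number 21) and 22648 (96.7%) had a value of shared sequence. All knockout-labelled libraries, both GW9662 libraries, the deeper vehicle library, the shallower IL-4 library, the deeper IL-4 plus GW9662 library and the shallower washed-out wild-type library are of the low kind. Part of the difference between genotypes is therefore tied to the kind. A fit with the kind as a term and comparisons within a kind were added for this reason.

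Reinforced genes had a level after the second exposure at least 2-fold over both the first exposure and unstimulated cells, and retained genes a level after washout at least 2-fold over or under unstimulated cells. Each set was chosen in 1 genotype and looked at in the other. Overlaps are given beside the product of the set sizes over the 11325 genes measured in both genotypes, with each set cut to those genes. Genes named in the genotype set were picked by a rule written after the values were seen.

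The 30 lists were Pparg alone, IL-4 and STAT6 markers, canonical PPARγ targets, LXR and cholesterol efflux, cholesterol synthesis, fatty acid oxidation, matrix remodelling, inflammatory genes, interferon-stimulated genes, class II antigen presentation, IL-4 signalling, macrophage identity, cell cycle, endoplasmic reticulum (ER) stress, NRF2 targets, heat shock and immediate early genes, glycolysis, oxidative phosphorylation, the citrate cycle, arginine and polyamines, lysosome, osteoclast genes, and markers of neutrophils, dendritic, T and NK, B, mast, eosinophil, stromal and erythroid cells. In the tables Chil3 is named Chi3l3 and Rnase2a is named Ear11.

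Alternatives planned were pseudocounts of 0.1 and 5 CPM, no filter or a filter of 5 CPM, 3-fold, trimmed-mean (30%) and upper-quartile rescaling, 1.5-fold for the memory sets, list members of at least 10 CPM, voom and leaving out each library. Those chosen after the data were seen were the fits without group weights and with counting kind, the removal of counting-sensitive genes, comparisons within a kind, and each restimulated library alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for all other steps. No batch or replicate label was available to adjust for. Results of 4 single genes are not reported here, though the genes stay in all fits, counts and lists.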

Results

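The series measured poly-A RNA in mouse bone marrow-derived macrophages by sequencing, in 2 experiments of 12 groups and 24 samples, with 2 samples per group. In the antagonist experiment, cells received vehicle, interleukin-4 (IL-4), the PPARγ ligand-site blocker GW9662, or both, for 24 h. In the memory experiment, wild-type cells and cells labelled as Pparg knockout were left alone or given IL-4 for 24 h and washed for 24 h, and were then read without or with 3 h of IL-4. The deposited tables hold 1 averaged column per group, from which the values of both libraries of a group were separated by their read steps. Libraries held 15766734 to 27973240 reads in genes in the antagonist experiment and 5444284 to 16476513 in the memory experiment. Log2 ratios below come from the authors' means with 1 CPM added, which understates changes of low genes. Standard errors (SE) and Benjamini-Hochberg (BH) adjusted p come from limma on the separated libraries, and "rose" and "fell" are used for genes with adjusted p under 0.05. The labels do not say whether the samples of a group came from separate animals or cultures, so each p measures the spread between these samples only, which may be technical. Where a group's value could not be separated, the spread of that group did not enter the test.

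Pparg itself, the gene of the lipid-sensing nuclear receptor under study, rose with IL-4 at 24 h from 29.2 to 105 CPM (log2 ratio 1.82, SE 0.20, adjusted p = 0.0011 by limma). The IL-4 libraries read 132 and 78.7 CPM. Pparg stood at 27.8 CPM with GW9662 alone and at 129 CPM with IL-4 plus GW9662. In the memory experiment, wild-type Pparg was 23.0 CPM unstimulated, 24.7 after a first IL-4 exposure, 20.8 after pretreatment and washout, and 34.0 after a second exposure. The knockout-labelled cells read 21.1, 27.6, 26.6 and 40.9 CPM in the same order. None of the 4 differences between genotypes passed in limma (adjusted p = 0.54 for unstimulated cells). The labels do not state which part of the gene was deleted, so reads over Pparg do not test the knockout. In knockout-labelled cells Pparg rose with the first exposure (log2 ratio 0.37, adjusted p = 0.029), was higher at the second than at the first (0.55, adjusted p = 0.0077) and rose on restimulation (0.60, adjusted p = 0.0023).

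A day of IL-4 gave macrophages the alternatively activated pattern, with Retnla and Arg1 leading and interferon genes receding. Retnla, which encodes the secreted resistin-like protein RELMα, went from 5.22 to 18412.5 CPM (log2 ratio 11.53, SE 0.51, adjusted p = 0.00017 by limma). Its IL-4 libraries could not be separated, so their spread did not enter that test. Arg1, the arginine-splitting enzyme, went from 0.146 to 775 CPM (9.40, SE 0.27, adjusted p = 5.1e-06), and Ear11, an eosinophil-type ribonuclease, reached 568 CPM. Of the 11140 genes compared, 732 lay beyond 2-fold higher and 731 beyond 2-fold lower, and limma called 1090 higher and 933 lower.

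Further genes that led the rise were Tmem26, a membrane protein (log2 ratio 7.48), Fn1, the matrix protein fibronectin (7.22, SE 0.70), Pdcd1lg2, the PD-1 ligand PD-L2 (6.94), Flt1, a VEGF receptor (6.93), and Ocstamp, which drives cell fusion (6.78, to 125 CPM). The list of known IL-4 and STAT6 markers had 28 of its 36 measured members beyond 2-fold higher and 2 lower, with a median log2 ratio of 3.67. Limma called 28 of them higher and 1 lower, or 29 and 2 when adjusted over the list alone. Among IL-4 signalling components, the feedback inhibitors Cish (5.59), Socs1 (5.20) and Socs2 (3.82) rose, while Il13ra1, the other receptor chain for IL-4 and IL-13, fell from 15.5 to 0.884 CPM. That list of 18 had 4 calls each way (5 and 4 adjusted over the list alone) and a median of -0.03. In the arginine and polyamine list, 5 of 11 rose (5 adjusted over the list alone), among them the arginine importer Slc7a2 (6.17) and the creatine-pathway enzyme Gatm (2.16).

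Genes of cell fusion and bone resorption rose too, namely Dcstamp, a fusion receptor (log2 ratio 4.26), Atp6v0d2, a proton pump subunit (3.61), the integrin chain Itgb3 (2.90) and the protease Ctsk (2.43). The osteoclast and giant-cell list of 9 had a median of 2.43, with 6 calls up and 1 down by limma (6 and 2 adjusted over the list alone). Canonical PPARγ targets had 10 of 21 members up and none down, also adjusted over the list alone, with a median of 0.47. They include Fabp4, a fatty acid carrier (2.29, adjusted p = 0.013), the lipase Lpl (1.93, adjusted p = 0.014), and Adipoq, an adipokine listed at 0 in vehicle and at 5.55 CPM with IL-4. In the list for cholesterol efflux through LXR, the sterol exporter Abcg1 rose from 199 to 875 CPM and the desaturase Scd2 rose by 2.46 in log2. That list had 6 calls up and 3 down of 12 (6 and 5 adjusted over the list alone), with a median of 0.50. Of 32 matrix-remodelling genes, 13 rose and 6 fell (14 and 8 adjusted over the list alone).

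Interferon-stimulated genes fell, with 21 of 28 beyond 2-fold lower, a median log2 ratio of -2.21, and 22 calls down and none up by limma (25 adjusted over the list alone). Ifit3, an antiviral effector, fell from 169 to 4.12 CPM (-5.06, SE 0.35, adjusted p = 0.00015), and Ifit2 (-3.88) and the chemokine Cxcl10 (-4.38) fell with it. Of 18 inflammatory genes, 9 fell (10 down and 1 up adjusted over the list alone), including the cytokine Il1b (-3.90), the inflammasome sensor Nlrp3 (-2.55) and the chemokine Ccl3 (-2.29). Macrophage identity genes had 9 of 18 down and 2 up (9 and 4 adjusted over the list alone), among them the endotoxin co-receptor Cd14 (-3.21), the Fc receptor Fcgr1 (-2.54) and the chemokine receptor Ccr2 (-2.02). Other strong falls were in Gpr162, an orphan receptor (-4.93), the C-type lectin Clec4n (-4.77), the adhesion receptor Emr4 (-4.76), the fractalkine receptor Cx3cr1 (64.7 to 1.92 CPM), the protease inhibitor Ctla2b (-4.44) and the surface antigen Ly6a (-4.43). In the class II antigen presentation list, H2-DMa, a peptide loader, rose (1.96) while the co-stimulators Cd80 (-1.83) and Cd86 (-1.66) fell, with 2 calls each way of 10 (4 and 2 adjusted over the list alone). These counts depend on the IL-4 group, whose libraries differ most in this table, since limma called 764 to 1627 genes when 1 library was left out. Without group weights it called 3591.

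GW9662 alone gave no gene that limma called, with 257 genes at an unadjusted p under 0.05, 0 calls by voom and 10938 genes compared. By the fold alone, 1 gene lay beyond 2-fold higher and 254 lower, but 249 of the 254 were sensitive to counting, as described in the methods. Ubb, a ubiquitin gene with sequence copies elsewhere, read 4.6 and 458 CPM in the vehicle libraries. Its ratio of -5.37 became 0.01 without the shallower vehicle library. Of genes not sensitive to counting, Retnla stood at 5.22 CPM in vehicle and 12.5 with GW9662 (log2 ratio 1.12, SE 0.24, adjusted p = 0.99), and Saa3, an acute-phase protein, at 77.3 and 26.0 CPM (-1.53, SE 0.38, adjusted p = 0.99). The vehicle libraries read 118 and 36.8 CPM for Saa3. Il1b (-0.78), the antiviral synthetase Oas1a (-0.64) and Ifit3 (-0.59) also lay lower without passing. The lectin Mgl2 turned from -0.77 to 0.50 within libraries of the low kind, with 8.09 and 33.7 CPM in the vehicle libraries. With counting kind as a term, which leaves 3 degrees of freedom, limma called 12 genes higher and 19 lower. Adjusted p in that fit were 3.4e-09 for Retnla, 9.5e-24 for Saa3, 0.0055 for Il1b and 0.018 for Mgl2, then higher. Values so small rest on a variance shared across genes, not on 3 degrees of freedom alone. They do not measure the spread of Saa3 between the vehicle libraries. Interferon-stimulated genes had a median of -0.24, at percentile 0.0 of random lists matched for expression, and none of the 28 was called, nor was any adjusted over the list alone. The IL-4 marker list had a median of -0.01 and the canonical PPARγ targets one of 0.06, with no calls in either, also adjusted over the list alone.

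Adding GW9662 to IL-4 left 1 of 10867 genes beyond 2-fold, though with 1 library left out this ranged from 0 up and 258 down to 324 up and 0 down. Limma called 0 genes, with 1 at an unadjusted p under 0.05 and 0 by voom. Retnla stood at 18412.5 CPM with IL-4 and 22256.1 with both agents. The ribosomal precursor Rn45s (0.66) and the nuclear RNA Malat1 (0.54) had the highest ratios that the naming rule took up, and none of its lowest went under -0.37, that of the ribosome assembly gene Urb1, each with adjusted p of 1. The test of whether the IL-4 response differed with GW9662 gave 0 limma calls, 13 genes at an unadjusted p under 0.05 and 0 calls by voom. In that test, 260 genes lay beyond 2-fold, 251 of them sensitive to counting. Outside those, Saa3 (difference of log2 ratios 1.33), Malat1 (1.04), the interferon-induced GTPase Iigp1 (1.01) and Ifit3 (1.00) were highest and Retnla (-0.84, SE 0.56, adjusted p = 1) lowest. With counting kind as a term, limma gave Saa3 an adjusted p of 0.0026, which also rests on a variance shared across genes. The spread between the IL-4 libraries limits this comparison, so a gene without a call is not shown to respond alike.

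A first 3 h of IL-4 in wild-type cells gave a sharp early response led by feedback inhibitors. Socs1, which dampens cytokine receptors, went from 0.917 to 268 CPM (log2 ratio 7.13, SE 0.12, adjusted p = 9.9e-16 by limma). Rasgrp1, a Ras activator, was listed at 0 before and stood at 112 CPM after. Nfkbiz, a co-factor of inflammatory transcription, fell from 39.6 to 2.53 CPM (-3.52, SE 0.15, adjusted p = 1.8e-11), and Abca1, a cholesterol exporter, from 210 to 21.4 CPM. Of 11345 genes, 552 lay beyond 2-fold higher and 409 lower, and limma called 2824 higher and 2870 lower (2949 in all without group weights).

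Early induced genes included Cish (log2 ratio 6.65), Arg1 (6.26, to 108 CPM), Pdcd1lg2 (6.04), the monocyte chemokine Ccl7 (5.72), Slc7a2 (5.13) and Socs2 (5.08). The IL-4 marker list had 25 of 33 members beyond 2-fold higher and a median of 2.91, with 28 calls up and 1 down (29 and 1 adjusted over the list alone). The adhesion protein Cdh1 was listed at 0 before and read 27.8 CPM after, and the growth factor Hbegf rose by 4.09. Inflammatory genes were divided, as Ccl2, a monocyte attractant, and the co-stimulatory receptor Cd40 rose (3.26 and 3.12) while the cytokine Tnf (-1.95) and Ccl3 (-1.62) fell. That list of 18 had 4 calls up and 8 down, also adjusted over the list alone. Interferon-stimulated genes had 9 calls up and 2 down of 28 (also adjusted over the list alone), among them the regulator Irf7 (1.93) and the nucleic acid sensor Zbp1 (1.79). The receptor chain Il4ra rose by 1.78, to 1029.9 CPM.

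Other early falls were those of the lysophosphatidic acid receptor Lpar6 (log2 ratio -2.86), the chemokine receptor Cxcr4 (-2.78), Cx3cr1 (-2.75), the potassium channel Kcnj2 (-2.62), the membrane protein Lhfpl2 (-2.59) and the iron exporter Slc40a1 (-2.58). Among identity genes the efferocytosis receptor Mertk (-1.69) and Ccr2 (-1.58) fell, with 4 calls up and 6 down of 18 (also adjusted over the list alone). Canonical PPARγ targets had 4 up and 7 down of 22, also adjusted over the list alone. The crosslinking enzyme Tgm2 rose by 1.45 and Abcg1 by 1.37.

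Knockout-labelled cells gave a first response of similar make-up. Socs1 rose from 0.923 to 282 CPM (log2 ratio 7.20, SE 0.13, adjusted p = 1.6e-15 by limma), and Rasgrp1 went from 0.0913 to 144 CPM. Cish (6.22), Arg1 (6.13), Pdcd1lg2 (6.04), Ccl7 (5.53), Slc7a2 (5.52) and Tmem26 (5.50) rose, and Nfkbiz (-3.49), Abca1 (-3.17), Cxcr4 (-2.76), Cx3cr1 (-2.65), Lpar6 (-2.54), the kinase Stk17b (-2.52) and Slc40a1 (-2.49) fell. Limma called 2393 genes higher and 2539 lower of 11208 (2687 in all without group weights), and 506 and 410 lay beyond 2-fold. The IL-4 marker list had a median of 2.85, with 28 of 32 up and 1 down (29 and 1 adjusted over the list alone). In the test of the difference between genotypes, limma called 1 gene higher and 3 lower of 11494 (1 to 13 in all when 1 library was left out), with 1447 at an unadjusted p under 0.05 and 1 call by voom. Those 4 genes are given in the closing section. In that test the IL-4 marker list had no calls, also adjusted over the list alone.

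After 24 h of IL-4 and 24 h of washout, wild-type cells carried high levels of many IL-4 genes. Retnla stood at 2760.4 CPM against 5.38 in cells never exposed (log2 ratio 8.76, SE 0.32, adjusted p = 4.4e-10 by limma), and the chitinase-like Chi3l3 at 701 against 23.8 CPM (4.82, SE 0.13, adjusted p = 6.2e-12). For Retnla the washed-out libraries could not be separated, so their spread did not enter its test. Genes of class II antigen presentation were high, with H2-Aa at 1160.3 against 162 CPM (2.84, SE 0.13, adjusted p = 1.1e-09). Ly6a was low, at 13.6 against 140 CPM (-3.27). Of 11369 genes, 179 lay beyond 2-fold higher and 151 lower, and limma called 864 higher and 833 lower (733 in all without group weights).

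The class II list had 7 of 10 members beyond 2-fold higher and a median log2 ratio of 2.28, with 8 limma calls up and none down (8 and 1 adjusted over the list alone). H2-Ab1 (2.82), its master regulator Ciita (2.79) and H2-Eb1 (2.74) were among them. The clotting factor genes F7 (3.84) and F10 (3.09), the fatty acid hydroxylase Cyp4f18 (3.27) and Mgl2 (3.27) rose. The chitinase-like Chi3l4 read 34.0 against 2.44 CPM (3.35, adjusted p = 0.16) and is sensitive to counting. It read -0.69 in log2 without the deeper pretreated library. Of 32 matrix-remodelling genes 15 rose and 4 fell (17 and 6 adjusted over the list alone, median 0.48), and of 9 osteoclast genes 6 rose and 1 fell (also adjusted over the list alone, median 1.08). Fn1 (2.77), Atp6v0d2 (2.69), Ctsk (2.27) and the collagenase Mmp8 (2.05) were among the genes that rose. The LXR and efflux list had 8 of 12 up (8 adjusted over the list alone, median 0.69), with Scd2 at 1.96 and Abcg1 at 1.24. Canonical PPARγ targets had 8 up and 1 down of 20 (11 and 2 adjusted over the list alone), with the fatty acid carriers Fabp5 (1.23) and Fabp4 (8.80 to 20.0 CPM). Lower after washout were the repair enzyme Ung (-2.02), the ion exchanger Slc24a3 (-1.92), the cell-cycle gene Cdca7 (-1.87), the inhibitor of differentiation Id3 (-1.85), Ctla2a (-1.84), the cyclin Ccnd1 (-1.79) and the kinase Dmpk (-1.72). The counts lean on the pretreated libraries, of which 1 is of the low counting kind, and 68 of the 151 lower genes were sensitive to counting. Leaving out 1 library gave 277 to 726 genes beyond 2-fold.

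Knockout-labelled cells had much the same genes raised after washout. Retnla stood at 2384 against 2.56 CPM (log2 ratio 9.39, SE 0.27, adjusted p = 1.7e-11 by limma) and Chi3l3 at 431.0 against 13 CPM (4.95). Mgl2 (3.72), Cyp4f18 (3.64), F7 (3.02), F10 (2.75), the integrin Itgax (2.55, to 397 CPM), H2-Ab1 (2.50), Ciita (2.46), the invariant chain Cd74 (2.40), H2-Aa (2.39) and Atp6v0d2 (2.38) rose. Ly6a (-2.80), Ctla2a (-2.31), the sialic acid hydroxylase Cmah (-1.88), Slc24a3 (-1.61), the organic anion carrier Slco2b1 (-1.55), Dmpk (-1.41), the metal-binding Mt2 (-1.34), the lectin Siglece (-1.32) and Ccnd1 (-1.32) fell. Limma called 1073 genes higher and 1174 lower of 11230 (577 in all without group weights), and 167 and 52 lay beyond 2-fold. Of the 179 genes retained beyond 2-fold in wild type, 123 were also among the 167 retained in knockout-labelled cells, where independent lists of the 177 and 166 that were measured in both genotypes would share 2.59. All 179 lay in the same direction in the knockout-labelled cells, with a median of 1.21 there. For lower genes, 39 were shared between the 151 and the 52, against 0.527 for independent lists of the 117 and 51 measured in both genotypes. The test of the difference in the pretreatment effect gave 1 limma call of 11507, and 0 to 507 when 1 library was left out, with 899 genes at an unadjusted p under 0.05 and 0 by voom. Retnla had adjusted p = 0.69 in that test.

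**Figure D1:**
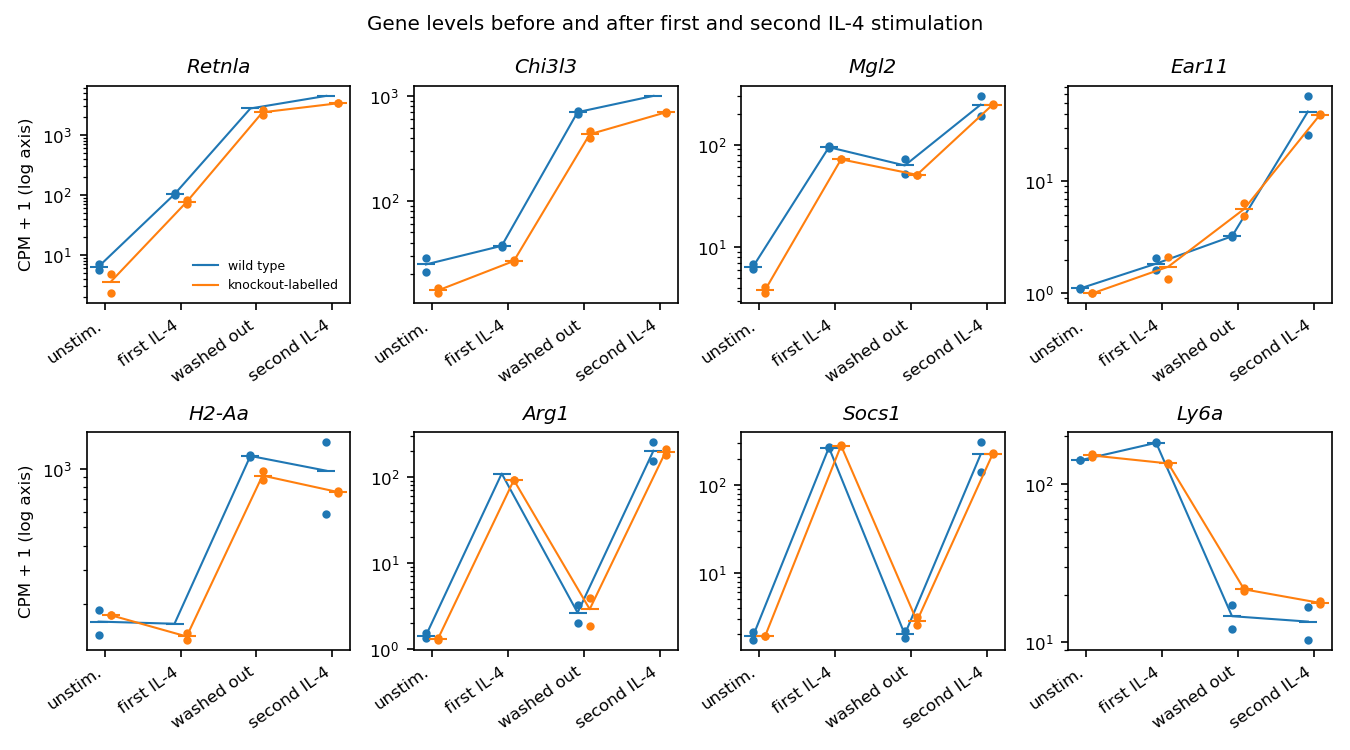
CPM plus 1 on a log axis for 8 genes over the 4 conditions of the memory experiment, with wild type in blue and knockout-labelled cells in orange. Dashes are the authors' means and points the separated libraries, which show the levels after washout and at the second exposure.

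After a second IL-4 exposure Retnla and Chi3l3 in wild-type cells stood far above their levels after the first, and most of that was there before it, as the washed-out cells read 2760.4 and 701 CPM. Chi3l3 stood at 1003 CPM after the second and 36.3 CPM after the first (log2 ratio 4.75, SE 0.34, adjusted p = 7.2e-06 by limma), and Retnla at 4479.6 and 102 CPM (5.45, SE 0.84, adjusted p = 0.0094). For neither gene could the restimulated libraries be separated, so their spread did not enter these tests. Ear11 read 40.9 against 0.842 CPM (4.51, adjusted p = 0.0033). Ly6a was lower, at 12.5 against 180 CPM (-3.74, SE 0.32, adjusted p = 1.4e-05). Limma called 24 genes higher and 15 lower of 11880, while 805 and 108 lay beyond 2-fold. In simulated tables, where 200 other genes were changed in first-exposed wild-type cells, it called 26 of 11256 unchanged genes here. Single calls near the threshold therefore carry little weight.

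Class II genes were above the first exposure, as H2-Aa (log2 ratio 2.62, adjusted p = 0.003), H2-Ab1 (2.56), H2-Eb1 (2.51) and Cd74 (2.25) rose, and the list had 7 of 10 beyond 2-fold and a median of 1.64 (6 calls adjusted over the list alone). The deeper and shallower restimulated libraries read 584 and 1363 CPM for H2-Aa, 445 and 1088 for H2-Ab1 and 333 and 849 for H2-Eb1, so the size of these rises depends on the library. Ctsk (2.73), Atp6v0d2 (2.56) and Mmp8 (1.77) also rose, as did Fn1 (5.88, adjusted p = 0.015), though with 967 and 73.7 CPM in the restimulated libraries. Thbs1, a matrix glycoprotein, passed at 6.92 (adjusted p = 0.046), but its restimulated libraries could not be separated. Their spread did not enter that test, so the pass carries little weight. In knockout-labelled cells the ratio of Thbs1 was -1.50. Interferon-stimulated genes were lower, with 15 of 28 beyond 2-fold, a median of -1.07 and 4 limma calls (14 adjusted over the list alone). Oas3 (-2.48), the related synthetases Oasl2 (-1.90) and Oas2 (-1.59), the sialoadhesin gene Siglec1 (-1.78) and the sugar phosphate carrier Slc37a2 (-1.64) fell.

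Several genes with the highest means did not pass, since the libraries of the restimulated wild-type group were far apart. Col1a1, a fibrillar collagen, read 492 and 16.9 CPM in them against 2.40 CPM after the first exposure (adjusted p = 0.18). The growth factor Ctgf (log2 ratio 7.62), the protease inhibitor Timp3 (6.89) and the matrix protein Tnc (6.79) stood likewise. The stromal cell list had all 8 measured members beyond 2-fold, a median of 5.19 and 0 limma calls (8 adjusted over the list alone). Its member Dcn, a fibroblast proteoglycan, stayed under the filter at 0.791 and 0.329 CPM. With the deeper library alone, 1151 genes lay beyond 2-fold higher and 109 lower, with the shallower 382 and 645, and with either alone 187 and 49. The shallower library also had a trend with transcript length, taken out after the data were seen. Of 589 separated genes 2-fold lower in the shallower library but not in the deeper, 230 (39.05%) stayed so without that trend. Limma calls, 39 in all, depend on which library is left out. Without group weights they were 1212, where the simulation called 994 unchanged genes.

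In knockout-labelled cells 2514 genes passed in the same comparison, or 813 without group weights, and the simulation without change gave 0 either way. Retnla rose from 75.3 CPM at the first to 3377 CPM at the second exposure (log2 ratio 5.47, SE 0.28, adjusted p = 7.9e-09 by limma), Chi3l3 from 25.7 to 697 CPM (4.71) and Ear11 from 0.731 to 38.3 CPM (4.51). Cyp4f18 (3.43), the sodium channel Scn3a (3.20), F10 (2.62), F7 (2.62), Atp6v0d2 (2.62), H2-Aa (2.47), H2-Ab1 (2.45), Cd74 (2.35), Mmp8 (2.23), Scd2 (2.07), Abca1 (1.34) and Arg1 (1.09, adjusted p = 0.0051) rose. Ly6a (-2.92), Ctla2a (-2.10), the inhibitor of differentiation Id1 (77.7 to 18.6 CPM), Dmpk (-1.65), the catenin Ctnnd2 (-1.65), the oxysterol enzyme Ch25h (-1.64), the fatty acid receptor Gpr84 (-1.64) and Ccl2 (-1.22) fell. Of 11190 genes, limma called 1415 higher and 1099 lower. The IL-4 markers had 18 up and 3 down of 34 (19 and 5 adjusted over the list alone), the class II list 8 of 10 up (8 adjusted over the list alone) and the canonical PPARγ targets 16 up and 1 down of 21, also adjusted over the list alone.

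Genes at least 2-fold higher after the second exposure than after the first, and than in unstimulated cells, were termed reinforced. Wild type gave 690 of them and knockout-labelled cells 111, with 67 shared. Of the 11325 genes measured in both genotypes, 277 and 107 belong to these sets, and independent lists of those sizes would share 2.62. Of the 107, all were higher after the second than after the first exposure in wild type, with a median log2 ratio of 1.35. Of the 277, 192 (69.3%) were so in knockout-labelled cells, with a median of 0.42. Of all 690, including those not measured in knockout-labelled cells, 40.1% were so there, with a median of 0.00. Genes reinforced in wild type with either restimulated library alone numbered 147, of which 51 were reinforced in knockout-labelled cells, against 0.945 for independent lists of the 100 and 107 measured in both genotypes. Of these 51, 41 already lay at least 2-fold higher after washout than in unstimulated wild-type cells. The sets of the 2 genotypes share no libraries. The test of the difference between genotypes in the second against the first exposure gave 1 limma call, higher, of 11991, with 631 genes at an unadjusted p under 0.05 and 1 call by voom, lower. It gave 0 to 327 calls when 1 library was left out, and 2 higher and 53 lower with counting kind as a term. All libraries of each genotype in this test are of 1 kind. Counting kind as a term therefore cannot change its differences, only their variance and the genes tested. Retnla had adjusted p = 1 in the main test. The set size of 690 rests on the deeper library, as 271 genes were reinforced without it and 958 without the shallower.

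**Figure D2:**
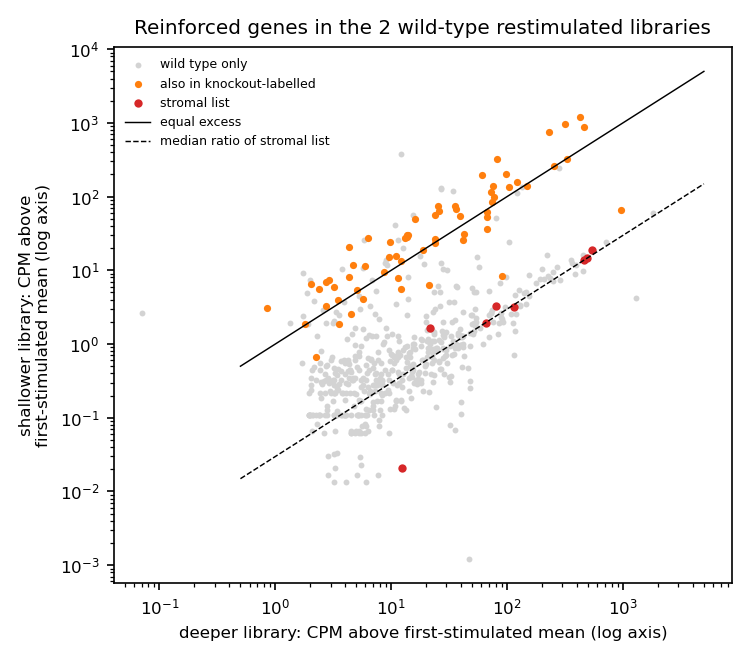
Excess CPM over first-exposed wild-type cells in the shallower restimulated library against the deeper, for the 589 of 690 reinforced genes that were separated and had an excess in both, 64 of them also reinforced in knockout-labelled cells and 8 of the stromal list. The solid line marks equal excess and the dashed line the median ratio of the stromal genes.

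Restimulated wild-type cells, set against washed-out cells, showed the early response again. Socs1 rose from 0.999 to 223 CPM (log2 ratio 6.81, SE 0.42, adjusted p = 3.6e-07 by limma). The matrix genes Tnc (7.34, adjusted p = 0.023), Timp3 (0.831 to 234 CPM) and Lox, a collagen crosslinker (6.89), passed as well, with the wide library spread described above. The potassium channel Kcnj10 (-2.78), the transcription factor Pou2f2 (-2.72), the orphan receptor Gpr141 (-2.64), Nfkbiz (-2.60), Cx3cr1 (-2.47), the antiviral Rsad2 (-2.36), the endosomal Zfyve28 (-2.31) and the bacterial lipid sensor Tlr2 (-2.21) fell. The IL-4 marker list had 20 of 33 up and none down (23 adjusted over the list alone), with a median of 2.43. Limma called 339 genes higher and 285 lower of 11958 (4424 in all without group weights, where the simulation without change gave 993), and 312 to 1364 when 1 library was left out.

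In knockout-labelled cells restimulation raised Rasgrp1 (log2 ratio 6.73), Pdcd1lg2 (6.43), Socs1 (6.33, adjusted p = 2.1e-14 by limma), Arg1 (6.07), the homeobox gene Msx3 (5.99), Tmem26 (5.44), Scn3a (5.41) and Cish (4.85). Thbs1 (-4.02), Nfkbiz (-3.14), Gpr162 (-2.94), Cx3cr1 (-2.93), Slc40a1 (-2.44) and Abca1 (-2.27) fell. Of 34 IL-4 markers, 29 rose and none fell, also adjusted over the list alone. Limma called 2180 genes higher and 1867 lower of 11282 (2070 in all without group weights). Whether the wild-type response to the second exposure differed from that to the first was tested too. Of 12074 genes, 3 had limma calls, all 3 lower, with 748 at an unadjusted p under 0.05 and 5 calls by voom. Without group weights there were 99 calls of either direction, where the simulation called 96 unchanged genes. The 3 include the PD-1 ligand Cd274 (limma difference -2.40, adjusted p = 0.02). Retnla (-3.31, adjusted p = 0.28) and Mgl2 (-1.90, adjusted p = 0.21), already high before restimulation, did not pass.

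**Figure D3:**
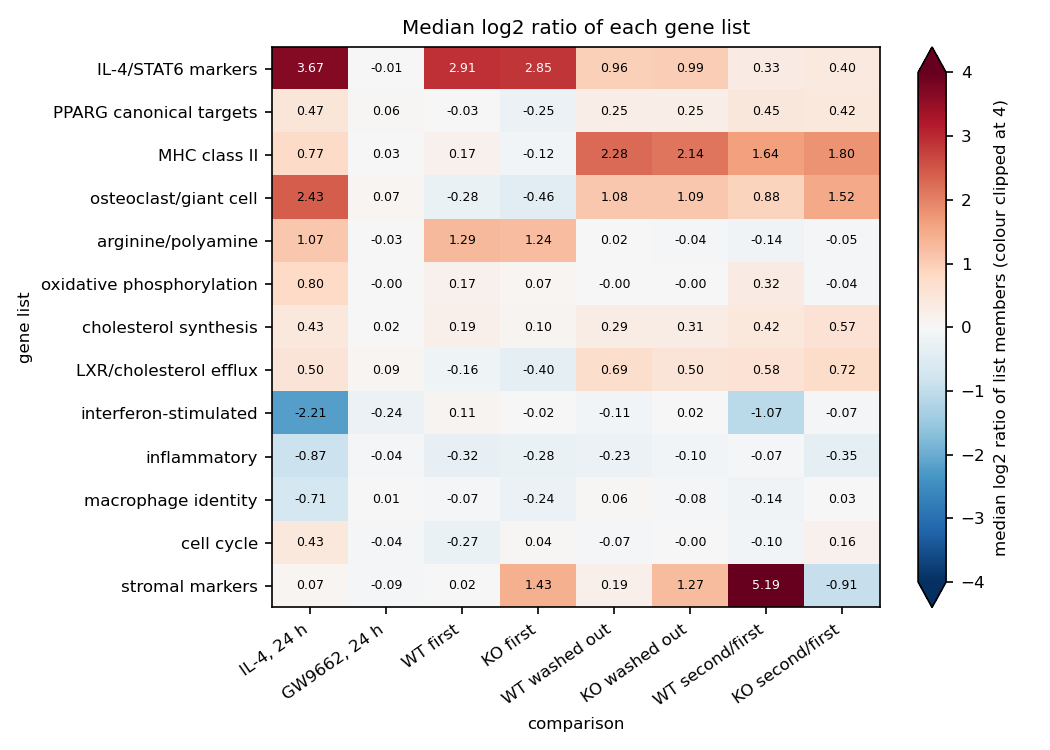
Median log2 ratios of 13 gene lists (vertical) in 8 comparisons (horizontal) as a heat map. IL-4 markers stand high in the comparisons of IL-4 with its control.

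Set against wild type, unstimulated knockout-labelled cells nearly lacked Lyz2, and many other differences were tied to the counting kind. Lyz2, the main macrophage lysozyme, read 30727.3 CPM in wild type and 41.8 in knockout-labelled cells (log2 ratio -9.49, SE 0.24, adjusted p = 2.6e-10 by limma). Its wild-type libraries could not be separated in any condition, so their spread enters none of its p-values here or below. Htatip2, a metastasis suppressor, read 68.8 and 9.05 CPM (-2.79, SE 0.12, adjusted p = 2.6e-10). Saa3 stood higher, at 18.5 against 2.25 CPM (2.58, SE 0.32, adjusted p = 7.0e-05). Of 11280 genes, 8 lay beyond 2-fold higher and 431 lower, but 378 of the 431 were sensitive to counting.

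The adhesion receptor Vcam1 (log2 ratio -2.58), the growth factor Gdf3 (-2.06), the chromatin protein Hmgb3 (-2.03), the ubiquitin-like gene Uevld (-1.85), the lectin Clec4b1 (-1.64) and the efferocytosis receptor Axl (-1.53) were lower. The semaphorin receptor Plxnd1 (1.35, to 1062 CPM), the haem-binding Hebp1 (17.5 to 37.4 CPM), the GTPase Rhoh (0.90), the folate receptor Folr2 (0.89), the phagocytic bridge Mfge8 (0.82) and the elastase Mmp12 (0.76) were higher. Among IL-4 markers Retnla (-0.84, adjusted p = 0.021), Chi3l3 (-0.82) and Mgl2 (-0.75) were lower, while that list of 26 had 7 calls up and 4 down (8 and 4 adjusted over the list alone). Limma called 901 genes higher and 1206 lower (345 in all without group weights). With counting kind as a term it called 20. The effect of kind then comes from the washed-out wild-type libraries alone, as no other memory group holds both kinds. Any other difference between those libraries thus enters the genotype differences of unstimulated cells. Lyz2, not separated in wild type, was not tested in that fit. All knockout-labelled libraries were of the low counting kind, and Ppia (-6.39), Entpd4 (-6.04) and Ubb (-5.96) are sensitive to counting.

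After the first IL-4 exposure the same genes led, with Lyz2 at 21.2 against 24471.3 CPM (log2 ratio -10.11, adjusted p = 1.9e-10 by limma), Htatip2 (-3.20), Vcam1 (-2.23), Clec4b1 (-2.03), Gdf3 (-1.81) and Axl (-1.60) lower. The repair gene Mbd4 (1.04), Mmp12 (0.90) and Plxnd1 (0.78) were higher. Limma called 179 higher and 856 lower of 11245 (279 in all without group weights), or 13 in all with counting kind as a term. IL-4 markers had 5 up and 3 down of 33 (7 and 3 adjusted over the list alone).

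After pretreatment and washout, Lyz2 (log2 ratio -9.40, adjusted p = 8.9e-09 by limma), Htatip2 (-2.66), Vcam1 (-2.34), Uevld (-1.83), Gdf3 (-1.49), Axl (-1.26) and Slco2b1 (-1.21) were lower in knockout-labelled cells. Saa3 (3.24, adjusted p = 0.00072), the scavenger protein Cd5l (96.5 to 317 CPM, 1.70), Folr2 (1.57), Id3 (1.33), Mfge8 (176 to 367 CPM), Irf7 (1.00), Itgax (0.97) and the protease Plau (0.86) were higher. The lectin Clec10a (-0.72, adjusted p = 0.027) and the transglutaminase F13a1 (-0.84) were lower. Limma called 179 genes higher and 244 lower of 11347 (33 in all without group weights), and 271 of the 296 genes beyond 2-fold lower were sensitive to counting. Within libraries of the low kind, 27 lay beyond 2-fold higher and 28 lower. Inflammatory genes had 5 of 16 up and none down (6 adjusted over the list alone), and the IL-4 markers 4 up and 2 down of 32 (11 and 3 adjusted over the list alone). Leaving out 1 library gave 54 to 672 limma calls.

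After the second exposure, 36 genes lay beyond 2-fold higher and 1141 lower in knockout-labelled cells, while limma called 0 higher and 3 lower (1297 in all without group weights, where the simulation without change gave 859). Of the 1141, 406 were sensitive to counting. The split rests on the deeper restimulated wild-type library, as 615 genes lay higher and 676 lower without it. At an unadjusted p under 0.05 there were 1064 genes, and voom called 305. Lyz2 was among the 3 (14.5 against 21966 CPM, log2 ratio -10.47, adjusted p = 0.0001). Saa3 (2.45, adjusted p = 0.5) and Oas3 (1.40, adjusted p = 0.15) did not pass. The matrix list had 17 of 39 beyond 2-fold lower and the stromal list all 8, with 0 limma calls in either (4 up and 15 down, and 8 down, adjusted over the list alone). Across the first 3 conditions 279 genes lay beyond 2-fold the same way, and 9 of them, 8 lower and 1 higher, also did so within libraries of the low kind or, for Lyz2, could not be separated. Those 9 are Lyz2, Htatip2, Vcam1, the integrin Itgad, Gdf3, the zinc finger Zxda, Uevld, Axl and, higher, the lectin-region transcript BC064078, with Itgad and Zxda sensitive to counting.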

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

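The tests in this part were chosen after the results were seen, apart from the tests of differences between responses, which were planned as comparisons and given a limma test later. The 9 genes named here had adjusted p under 0.05 in limma in a test that asks whether a response differs between groups. Those tests gave 3, 4, 1 and 1 calls in the order below. Of 11256 unchanged genes in simulated tables, limma called 18, 6, 0 and 19 in them. The tests with 18, 6 and 19 use first-exposed wild-type cells, where 200 other genes were changed, which eases the adjusted threshold. These counts are thus not those of tables without any change, and they do not set the 1 call for the effect of pretreatment apart. They still show that calls in the tests with 18, 6 and 19 can fall on unchanged genes.

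Cd274, the PD-1 ligand PD-L1, responded less to the second than to the first IL-4 exposure in wild-type cells, with a difference of -2.40 in log2 (adjusted p = 0.02). It stood at 27.7 CPM unstimulated, 239 after the first exposure, 78.7 after washout and 127 after the second. Nabp1, a single-strand DNA-binding protein, differed by -1.80 (adjusted p = 0.046), with 26.7, 129, 59.1 and 79.5 CPM in the same order. Slc37a2, the sugar phosphate carrier, differed by -1.50 (adjusted p = 0.042), with 310, 971, 272 and 312 CPM. By voom the adjusted p were 0.016, 0.036 and 0.051. With 1 library left out, adjusted p by limma ran from 1.2e-05 to 0.13, from 7.5e-05 to 0.2 and from 0.00032 to 0.13, so each call was stronger without some libraries and lost without others. The restimulated wild-type libraries that enter this difference are the least alike of the series.

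Between genotypes, 4 genes differed in the first response. Gm19434, an unnamed gene model, differed by -2.16 (adjusted p = 0.0013), but it was at 0 CPM in both knockout-labelled groups and at 0.104 and 3.92 CPM in wild type, so the difference is that 1 genotype shows the transcript at all. Its adjusted p was 0.022 at the highest with a library left out and 0.26 by voom. The unnamed transcript 8430419L09Rik differed by -1.30 (adjusted p = 0.026), at 18.5 and 43.2 CPM in wild type before and after IL-4 and at 12.3 and 11.3 CPM in knockout-labelled cells. Emp1, a membrane protein of epithelial junctions, differed by -0.60 (adjusted p = 0.026), at 479.6 and 462 CPM against 745 and 475 CPM. Spdl1, a spindle protein, differed by 0.87 (adjusted p = 0.028), at 39.2 and 21 CPM against 28.0 and 28.1 CPM. Voom gave 0.04, 0.058 and 0.058 for these 3, and with a library left out they reached 0.2, 0.16 and 0.23.

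Lyz1, a lysozyme whose sequence resembles that of Lyz2, differed by 0.68 between genotypes in the effect of pretreatment (adjusted p = 0.028). It went from 2552.8 to 1208 CPM in wild type and from 348 to 264 CPM in knockout-labelled cells. Lyz1 is sensitive to counting, and 1 of the wild-type libraries after washout is of the low kind, so the wild-type fall may be one of counting. Its washed-out wild-type value was unresolved, so voom used a guessed pair of counts there. Its adjusted p was 0.76 by voom and ran from 2.2e-05 to 0.29 with a library left out. Oas3, an antiviral synthetase, differed by 2.13 between genotypes in the second against the first exposure (adjusted p = 0.045). It went from 154 to 26.8 CPM in wild type and from 94.2 to 72.4 CPM in knockout-labelled cells. Its adjusted p was 0.072 by voom and 0.2 at the highest with a library left out.

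Of the 9, Gm19434 alone passed in limma with every library left out in turn, and it did not pass by voom. What makes the others depend on single libraries was not tested.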

How the results depend on the processing

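The tests without group weights, with counting kind, without counting-sensitive genes and within a kind were chosen after the results were seen, and the pseudocounts, filters, folds, rescalings, voom and the leaving out of libraries were planned. No paired analysis was possible because the columns carry no replicate numbers, and for the same reason the planned replicate block was not run. The planned limma camera test of lists was not run. Values below are numbers of genes unless said otherwise, counts beyond 2-fold take both directions together, and only results that moved by over 1.5 times, lost or gained a call, or turned are given.

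The pseudocount set many counts. With 5 CPM in place of 1, genes beyond 2-fold fell from 1463 to 966 for IL-4 against vehicle, from 255 to 144 for GW9662 alone, from 1 to 0 for GW9662 added to IL-4, and from 260 to 154 for the difference of IL-4 responses. For the first exposure they fell from 961 to 614 in wild type and from 916 to 607 in knockout-labelled cells, and after washout from 330 to 140 and from 219 to 88. For the second against the first exposure they went from 913 to 420 and from 256 to 106, and for restimulation from 1706 to 971 and from 650 to 401. The wild-type difference of restimulation and first response went from 920 to 445. Between genotypes, counts went from 439 to 280 unstimulated, 435 to 283 after the first exposure, 307 to 162 after washout and 1177 to 634 after the second exposure. The genotype differences in first response, pretreatment effect and second against first exposure went from 35 to 5, 101 to 26 and 762 to 301. Limma calls with 5 CPM rose from 39 to 100 for the wild-type second against first exposure and from 3 to 5 for restimulation against first response, and the 1 call for the genotype difference in second against first exposure was lost (0). Reinforced genes went from 690 to 319 in wild type, 111 to 49 in knockout-labelled cells and 67 to 33 shared. Genes retained up went from 179 to 85, 167 to 77 and 123 to 64 shared, and genes retained down from 151 to 55, 52 to 11 and 39 to 7 shared.

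With 0.1 CPM, counts rose to 6 for GW9662 added to IL-4, 548 for wild type after washout, 422 for knockout-labelled cells after washout, 471 for their second against first exposure, and 255 and 317 for the genotype differences in first response and pretreatment effect. The limma call in the genotype difference in second against first exposure was lost (0). Reinforced genes in knockout-labelled cells rose to 174, genes retained up to 363 in wild type, 351 in knockout-labelled cells and 210 shared, and genes retained down to 305, 121 and 63.

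At 3-fold the counts were 623 for IL-4 against vehicle, 141 for GW9662 alone and 147 for the difference of IL-4 responses. They were 299, 74, 489, 676 and 451 for the wild-type first exposure, washout, second against first exposure, restimulation, and restimulation against first response. In knockout-labelled cells they were 318, 65, 72 and 211 for the first 4 of these. Between genotypes they were 273, 281, 155 and 711 in the order of the conditions above, and 6, 7 and 418 for the differences in first response, pretreatment effect and second against first exposure. Reinforced genes numbered 423, 42 and 29 (wild type, knockout-labelled, shared), genes retained up 58, 57 and 41, and genes retained down 16, 8 and 4. At 1.5-fold those sets held 1040, 318 and 192, then 586, 575 and 372, then 667, 312 and 177.

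With a filter of 5 CPM, counts were 0 for GW9662 added to IL-4, 561 for the wild-type second against first exposure, 581 for restimulation against first response, 783 between genotypes after the second exposure, 13 and 427 for the genotype differences in first response and in second against first exposure, and 396 for genes reinforced in wild type. No filter changed no count by over 1.5 times. Trimmed-mean factors ran from 0.974 to 1.022 and upper-quartile factors from 0.958 to 1.042. Upper-quartile rescaling raised limma calls between genotypes after washout from 423 to 647, with 71.3% of them higher in place of 42.3%, and lost the call in the genotype difference in second against first exposure (0). Trimmed-mean rescaling moved the higher share of calls for knockout-labelled cells after washout from 47.8% to 59.5% (1284 up and 873 down). The larger share of calls changed direction in further comparisons. With upper-quartile rescaling the higher share went from 53.9% to 48.6% for IL-4 against vehicle, from 53.9% to 45.6% for restimulation in knockout-labelled cells (1854 up and 2215 down), from 42.8% to 52.3% between unstimulated genotypes (1224 up and 1118 down) and from 47.8% to 56.5% for knockout-labelled cells after washout. With trimmed-mean rescaling it went from 49.6% to 50.4% and from 48.5% to 54.2% for the first exposure in wild-type and knockout-labelled cells, from 54.3% to 45.7% for wild-type restimulation and from 42.3% to 51.6% between genotypes after washout. The directions of small differences in these comparisons thus rest on the scaling.

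Without group weights limma called 3591 genes for IL-4 against vehicle, 2949 for the wild-type first exposure, 733 after washout, 1212 for the second against the first exposure, 4424 for restimulation and 99 for restimulation against first response. In knockout-labelled cells it called 2687, 577, 813 and 2070 for the first 4 of these. Between genotypes it called 345, 279, 33 and 1297 in the 4 conditions, and 0, 0 and 3 for the 3 genotype differences. Voom called 426 for the wild-type second against first exposure, 5 for restimulation against first response, 201 and 305 between genotypes after washout and after the second exposure, and 1 and 0 for the genotype differences in first response and pretreatment effect.

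With counting kind as a term limma called 3262 genes for IL-4 against vehicle, 31 for GW9662 alone and 2 for the difference of IL-4 responses, 858 for wild type after washout, 141 for the second against the first exposure and 6 for restimulation against first response. Between genotypes it called 20, 13 and 5 unstimulated, after the first and after the second exposure, and 9, 4 and 55 for the 3 genotype differences. Of the 55, 53 were lower, while the 1 call of the main test was higher. In the tests that gave 141, 9 and 55, the libraries of each genotype are of 1 kind. There the term changed no difference, only the variance and the genes tested. With weights fitted anew, the same counts were 3157, 67, 2, 143 and 8 (washout left aside), 77, 26, 1563 and 8 between genotypes in the 4 conditions, and 9, 6 and 57. Genes with an unresolved value in a compared group, such as Lyz2 between genotypes, were not tested with this term, so part of a lower count can come from that. The antagonist fit has 3 degrees of freedom left with it. Single genes lost their calls under it: between unstimulated genotypes, adjusted p went from 9.1e-05 to 0.94 for Entpd4, 0.0002 to 0.55 for Ubb and 0.00017 to 0.59 for Fau. After the first exposure it went from 0.00023 to 1 for H2-Q1 and from 0.00028 to 1 for Rpl19.

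Without counting-sensitive genes, counts beyond 2-fold were 6 for GW9662 alone, 9 for the difference of IL-4 responses, 61, 61, 36 and 771 between genotypes in the 4 conditions, and 19 for the genotype difference in pretreatment effect, whose limma call was lost (0). Limma calls between genotypes after the first exposure were 457 in place of 1035, and genes retained down in wild type 83. Within low-kind libraries, counts were 12 for GW9662 alone, 10 for GW9662 added to IL-4, 67 for the difference of IL-4 responses and 55 between genotypes after washout.

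Leaving out each library in turn gave ranges of counts. The lone sample of the group kept the group weight fitted with both libraries, and the variance of each gene came from the other groups. Limma calls ran from 764 to 1627 for IL-4 against vehicle and from 0 to 1 for GW9662 alone, where 14 to 403 lay beyond 2-fold. Beyond 2-fold there were 20 to 324 for GW9662 added to IL-4 and 14 to 539 for the difference of IL-4 responses. In wild type the ranges were 277 to 726 beyond 2-fold and 870 to 1798 calls after washout, 11 to 378 calls for the second against the first exposure, 1471 to 2560 beyond 2-fold and 312 to 1364 calls for restimulation, and 0 to 365 calls for restimulation against first response. Knockout-labelled cells gave 1163 to 1598 calls after washout and 1519 to 1822 for the second against the first exposure. Between genotypes calls ran from 888 to 1551 unstimulated, 623 to 870 after the first exposure, 54 to 672 after washout (57 to 454 beyond 2-fold) and 2 to 346 after the second exposure. The genotype differences gave 36 to 90 beyond 2-fold and 1 to 13 calls in first response, 42 to 439 and 0 to 507 in pretreatment effect, and 0 to 327 calls in second against first exposure. Reinforced genes in wild type ran from 271 to 958 and genes retained down from 91 to 529. Directions moved as well. Without the deeper restimulated wild-type library, the higher share of genes beyond 2-fold went from 88.2% to 37.2% for the second against the first exposure, from 74.9% to 45.0% for restimulation, from 88.8% to 41.6% for restimulation against first response, from 3.1% to 47.6% between genotypes after the second exposure and from 9.2% to 71.6% for the genotype difference in second against first exposure. Without the deeper washed-out wild-type library it went from 54.2% to 27.1% after washout. For GW9662 added to IL-4 there were 0 up and 258 down without the shallower library of both agents, 1 up and 19 down without the shallower IL-4 library, 57 up and 0 down without the deeper library of both agents, and 324 up and 0 down without the deeper IL-4 library.

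Some log2 ratios turned with 1 library. For GW9662 alone, leaving out the shallower and the deeper vehicle library gave 0.12 and -6.89 for H2-Q1 (main value -5.90), 0.01 and -6.35 for Ubb (-5.37), 0.16 and -6.02 for Fau (-5.04), 0.06 and -6.00 for Rpl19 (-5.02), 0.09 and -5.88 for Ppia (-4.90) and 0.10 and -5.80 for Rpl5 (-4.83). For the difference of IL-4 responses, the ranges were -0.03 to 11.98 for H2-Q1 (5.99), -0.15 to 9.52 for Fau (5.05), -0.07 to 9.97 for Rpl19 (5.13) and -0.77 to 9.95 for Ppia (5.03). The lowest came without the shallower vehicle library for H2-Q1 and Fau and without the shallower library of IL-4 plus GW9662 for Rpl19 and Ppia. Chi3l4 after washout in wild type ran from -0.69 to 4.30 (3.35), and its genotype difference from -3.79 to 1.20 (-2.84), with the turn when the deeper washed-out wild-type library was left out. Without that library, Entpd4 and Ubb between genotypes after washout read 0.08 and 0.65 (main values -5.10 and -4.91), and without the shallower one -6.08 and -5.89.

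The stromal median turned without the shallower first-exposed knockout-labelled library, with ranges of -0.10 to 2.18 (1.43) for the knockout-labelled first exposure, -1.60 to 0.46 (-0.91) for its second against first exposure, and -0.16 to 2.14 (1.40) for the genotype difference in first response. The dendritic median for the knockout-labelled second against first exposure went from 0.62 to -0.64 with members of at least 10 CPM. Why single libraries differ was not tested here beyond the counting kinds, which by construction hold these sequence-sharing genes at different levels.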

Other observations

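All 13 tests in this part were chosen after the result they test was seen. Beyond the genes described above, a day of IL-4 raised genes of mitochondrial respiration, with 20 of 30 oxidative phosphorylation genes higher and none lower by limma (22 adjusted over the list alone, median log2 ratio 0.80). Atp5b, a subunit of ATP synthase, rose from 520 to 1470.1 CPM and Uqcrc1, of complex III, by 1.28. Of 17 citrate cycle genes 5 rose and 1 fell (9 and 2 adjusted over the list alone), with Mdh2 at 1.35. Of 21 fatty acid oxidation genes 7 rose (10 adjusted over the list alone), led by the co-activator Ppargc1b (3.10). Of 18 ER stress genes 7 rose (9 up and 2 down adjusted over the list alone), among them Sdf2l1 (2.63), Pdia4 (2.15) and Hyou1 (1.65). Heat shock and immediate early genes had 6 up and 1 down of 16 (also adjusted over the list alone), NRF2 targets 2 up of 18 (3 and 1), glycolysis genes 3 up and 5 down of 23 (6 each way), lysosome genes 5 up of 20 (6) and cell-cycle genes 6 up of 31 (6), the bracketed counts again adjusted over the list alone. Cholesterol synthesis had 5 of 21 up (5 adjusted over the list alone), with Mvd (1.34) and Sqle (1.07). At 3 h in wild type the cell-cycle list instead had 17 of 33 down and none up (17 adjusted over the list alone), with Ccne2 (-1.01) and Cdc6 (-0.96). Between unstimulated genotypes, 12 of 21 cholesterol synthesis genes were lower in knockout-labelled cells and none higher (12 adjusted over the list alone, median -0.25), while 12 of 20 lysosome genes were higher (12 adjusted over the list alone). With counting kind as a term 0 and 1 of these genes were called, and as all knockout-labelled libraries are of the low kind, genotype and kind are hardly separated here.

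Markers of other cells were measured in small numbers. For IL-4 against vehicle, neutrophil genes had a median log2 ratio of -0.85 over 11 genes, dendritic genes -0.51 over 6, T and NK genes -1.37 over 2 (with Cd4 at -3.76), B cell genes 0.15 over 2, the mast cell list 0.02 from 1 gene, eosinophil genes 0.18 over 4, stromal genes 0.07 over 2 and erythroid genes -0.92 over 3. Limma called 0, 0, 2, 1, 0, 0, 0 and 1 of them (0, 0, 2, 2, 0, 1, 0 and 1 adjusted over the list alone).

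With GW9662 alone 254 genes lay beyond 2-fold lower, and in knockout-labelled cells after washout 296 did. A candidate explanation is that reads were counted under another rule in part of the libraries, in the authors' processing. Of the genes lower with GW9662, 96.8% lay at least 2-fold lower in the low-kind than in the high-kind library of the washed-out wild-type group of the other experiment, where 1.21% of other genes did. For the knockout-labelled cells the share was 90.8% between the vehicle libraries (1.03% of other genes). Against the low-kind library of the control alone, 0.8% of the GW9662 genes and 6.5% of the knockout genes stayed 2-fold lower, which argues against an effect of the drug or the genotype on the rest, and which rule was used stays open.

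The 690 genes reinforced in wild type may hold RNA from stromal cells in the deeper restimulated library. There Col1a1 read 492 CPM and Tnc 392, and the excess of the 8 stromal genes in the shallower library was a median of 0.0298 of that in the deeper. Of the genes that held with either library but not in knockout-labelled cells, 70.5% had an excess at most 2 times that share, as did 0.0% of the 48 that held with either library and in knockout-labelled cells. Against stromal RNA, Dcn read 0.791 and 0.329 CPM. Genes reinforced through a single library were not tested, as their choice fixes that share. A trend with transcript length in the shallower library (Spearman correlation -0.685) does not remove the genes that held with either library, as 86.0% stayed 2-fold higher once it was taken out. Of the 51 that were reinforced in knockout-labelled cells too, 80.4% already lay at least 2-fold higher after washout than in unstimulated wild-type cells, so a level raised before the second exposure could account for most. A response at least 2-fold above the first was found for 19.6% of them (median difference in log2 0.06), which leaves a stronger response of cells exposed before open for a part. Whether stromal cells were present stays open, as Dcn was low and 3 of the list's genes were measured in unstimulated cells too. Col1a1, though, read 2.51 CPM in unstimulated wild-type cells against 492 in the deeper restimulated library.

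Lyz2 and a few other genes were lower or higher in knockout-labelled cells in each of the first 3 conditions. Counting does not account for Lyz2, which read 21450.7 CPM in the GW9662 libraries of the same kind, nor do fewer macrophages, since the other 17 identity genes had a median log2 ratio of 0.19. A possible explanation is DNA carried along with the altered alleles. Positions were taken for 30 genes that differed by 1.5-fold the same way in the 3 conditions and within the low kind, or were not separated. Genes sensitive to counting, and Pparg itself, were left out. Of the 30, 4 lay in 10 Mb of chromosome 7 (permutation p = 0.031 against 10000 random sets, whose mean was 2.34). Plxnd1, Gdf3 and Clec4b1, 3 of the 30, lay within 10 Mb of Pparg (permutation p = 0.0059, random mean 0.36). The window and the fold were chosen after the positions were seen, and an effect of the missing receptor could give such a set as well. With vehicle Lyz2 read 23273 CPM, near its GW9662 level, though 24 h of a blocker does not stand for a missing receptor. An allele placed at Lyz2, on chromosome 10, could account for Lyz2, but linked DNA there holds no genes of chromosomes 6 and 7. The median of 0.19 and these p-values leave the cause of the set open.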
